A study of Homo sapiens with 7 samples.

How the data were processed

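RNA sequencing was analysed for 7 libraries of the human cell line TE11, which the labels describe as esophageal squamous cell carcinoma cells. Of these, 3 libraries came from cells given 0.07% DMSO, the solvent (vehicle), and 4 from cells given 200 µM diclofenac, both for 48 h. Diclofenac is a nonsteroidal anti-inflammatory drug that inhibits the cyclooxygenases PTGS1 and PTGS2. Per the labels' protocols, total RNA was purified on columns and made into libraries with a directional (strand-keeping) kit. Whether the counting used the strand, and which aligner, counter and annotation were used, is not given in the sources used here. The submitters' processing notes name DESeq, with no version, and the mouse build GRCm38. The rows of the table carried human gene symbols, and 56530 of the 60591 rows (93.3%) matched the GENCODE human annotation by symbol or gene identifier. Because the build of the counting is open, no coordinates are given, and the annotation was used only for gene classes, exon lengths and pseudogene names.

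The values used were the raw counts per gene deposited by the authors, whole numbers with no normalization and 1 column per library. Total counts ran from 19878696 to 26490829 per library, so that 1 count was worth 0.0377 to 0.0503 CPM (a gene's counts relative to the library's total, on the usual scale) and 3 counts 0.113 to 0.151 CPM. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries of the same group differed beyond sampling noise, with a chi-square per degree of freedom of 2.17 to 7.41 over genes with at least 20 counts in the pair, so no library was treated as a repeat deposit of another.

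The comparison was diclofenac against vehicle, over all 7 libraries, with group as the only term. Genes were filtered with filterByExpr (a minimum count of 10 and a minimum total of 15), which left 18311 genes holding 99.86% of all counts. Counts were scaled by TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and standard errors (SE) of log2 fold changes were derived from the F statistic. Normalized CPM are CPM of the TMM-scaled library. A total of 30 gene lists were fixed before the data were examined, and the 27 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Their p-values were adjusted over those 27 lists. The p53 and metabolic lists are themes that the title of the series names, so they are not independent evidence of direction. Library measures were compared by exact two-sided permutation over the 35 splits of the 7 libraries into 3 and 4, whose smallest p is 0.0286.

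Genes named in the text followed a rule set before the data were examined. It took PTGS1, PTGS2, CDKN1A and MKI67 whatever their values, and 1 further gene that is not reported here. It then took the 6 largest rises and the 6 largest falls among called genes in the upper part of tested genes by mean expression (above the median) with no overlap between the groups. Last, it took the called members with the largest change, 2 for each of 11 main lists and 1 for each of 15 further lists. Genes outside the rule are named only where a count of 5 or fewer is spelled out or where the text says so, and they were then chosen after their values were seen.

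The steps were tested on simulated counts with the means and library sizes of these samples. Over 18002 genes, the edgeR test of diclofenac against vehicle recovered 24 of 50 genes changed 1.25-fold, 39 of 50 changed 1.5-fold, 45 of 50 changed 2-fold and 49 of 50 changed 4-fold. Of its 176 calls, 19 were of unchanged genes, a larger share than the 0.05 that the adjustment aims at. Few genes were changed, so the simulation did not test the scaling where 59.7% of genes are called, as here. Alternatives set before the data were examined were DESeq2 size factors and upper-quartile factors, the DESeq2 1.42.0 Wald test, limma with trend, no filter and a stricter filter (1 CPM in every library of a group), a minimum change of 2-fold, leaving out each library, the replicate number as a block, camera with an estimated correlation, and fry. Added after the data were seen were scaling by total counts alone, leaving out pseudogene rows, upper-quartile factors for the named genes, and the p53 list without members that also belong to the stress response.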

Results

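The series measured gene expression in TE11 cells under a vehicle (0.07% DMSO, n = 3) and under 200 µM diclofenac (n = 4) after 48 h. The title of the series names metabolic pathways and p53 signaling as the processes in question. Total counts were 26490829, 22364064 and 23775966 in vehicle replicates 1, 2 and 3, and 19878696, 23842247, 24985098 and 23860201 in diclofenac replicates 1 to 4. The difference between the group means gave an exact permutation p of 0.657. More genes had at least 1 count under diclofenac (30250 ± 391) than under vehicle (27110 ± 324). The exact permutation p was 0.0286, the smallest that 35 splits allow, or 0.0572 after adjustment over 6 library measures.

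Several genes that mark squamous epithelium were near or at 0 in every library, in both groups, while others were expressed. The basal keratins KRT5 and KRT14 had 0 and 3 counts in the 3 vehicle libraries together, and 1 and 2 counts in the 4 diclofenac libraries. KRT6A had no count in any library, and TP63, the p63 transcription factor of squamous cells, had 2 and 5 counts in the vehicle and diclofenac libraries. CDH1 (E-cadherin) stood at 2.26 ± 0.274 CPM and EPCAM at 1.85 ± 0.427 CPM in the vehicle libraries. Of 34 genes of squamous differentiation, 4 were at 1 CPM or more in every library and 6 were expressed highly enough to be tested. Of 20 genes of the basal list, 13 were at 1 CPM or more in every library and 15 were tested. Of all coding genes, 61.1% were at 1 CPM or more in every library, so the basal share is near that of coding genes at large. Among the expressed genes, named after their values were seen, were KRT10 at 26.8 ± 2.52, LAMA3 at 27 ± 2.59 and SOX2 at 12.8 ± 1.02 CPM in the vehicle libraries. The text therefore speaks of the libraries labelled TE11.

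**Figure D1:**
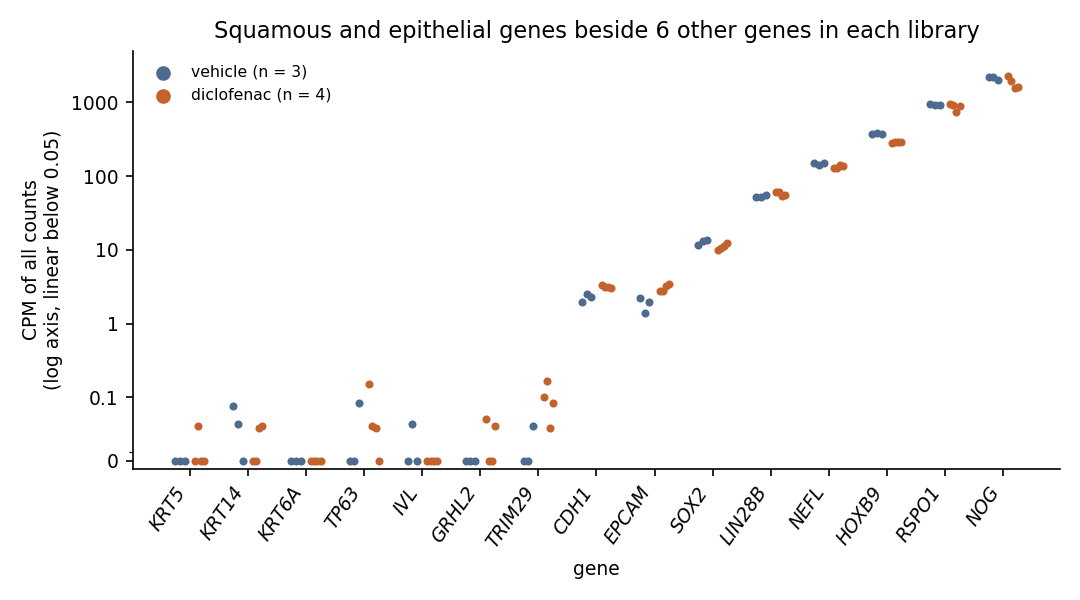
CPM of all counts (vertical axis, logarithmic above 0.05 and linear below) of 15 genes in the 3 vehicle libraries and the 4 diclofenac libraries, 1 point per library. KRT5, KRT14, KRT6A and TP63 stay at or below 0.151 CPM in every library, while NOG reaches 2300 CPM. GRHL2, TRIM29, CDH1, EPCAM and the 5 genes on the right were picked after the data were examined. Other expressed members of the squamous lists, such as KRT10 and LAMA3, are not shown.

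In the libraries labelled TE11, diclofenac was accompanied by lower transcripts of glycolysis, the tricarboxylic acid cycle, DNA replication and nucleotide synthesis and by higher transcripts of p53 targets and of the ATF4 stress response. The glycolytic enzyme PKM fell from 2455 ± 94.4 to 1297 ± 28.5 normalized CPM (SD, n = 3 and 4), and the thymidine kinase TK1 fell from 268 ± 3.78 to 136 ± 6.97. The stress-response gene NUPR1 rose from 1.24 ± 0.152 to 22.8 ± 2.35 normalized CPM, and SESN2, a p53 and ATF4 target that restrains mTORC1, rose from 123 ± 1.37 to 320 ± 10.8. The 13 mRNAs encoded by the mitochondrial genome rose, whereas 46 of 50 respiratory chain genes of the nucleus fell (camera adjusted p = 0.456 and 0.168 with an estimated correlation). In all, 10937 of 18311 tested genes (59.7%) changed by edgeR at an adjusted p under 0.05, with 5535 higher and 5402 lower under diclofenac.

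Most of these changes were small, with a median absolute log2 fold change of 0.429 among called genes. Of the called genes, 1194 were higher and 109 lower by at least 2-fold, and 2487 were higher and 1088 lower by at least 1.5-fold. The 2-fold rises lay mainly among weakly expressed genes: 706 of them had a mean below 0 log2 CPM, where the median log2 fold change was 0.42. Among the 643 genes with a mean of 8 log2 CPM or more the median was -0.29. The filter, met by any 3 libraries, lets weak genes in more easily through the 4 diclofenac than through the 3 vehicle libraries. In 58.5% of tested genes the libraries of the groups did not overlap, against 5.71% by chance. The first principal component, with 70.9% of the variance, separated the groups. The split into higher and lower depended on the scaling. It was 8635 against 3029 by total counts alone, which moved the median log2 fold change of all genes by 0.181, and 6994 against 4171 with upper-quartile factors, against 5535 and 5402 with TMM factors, so directions below are relative to the bulk of genes.

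**Figure D2:**
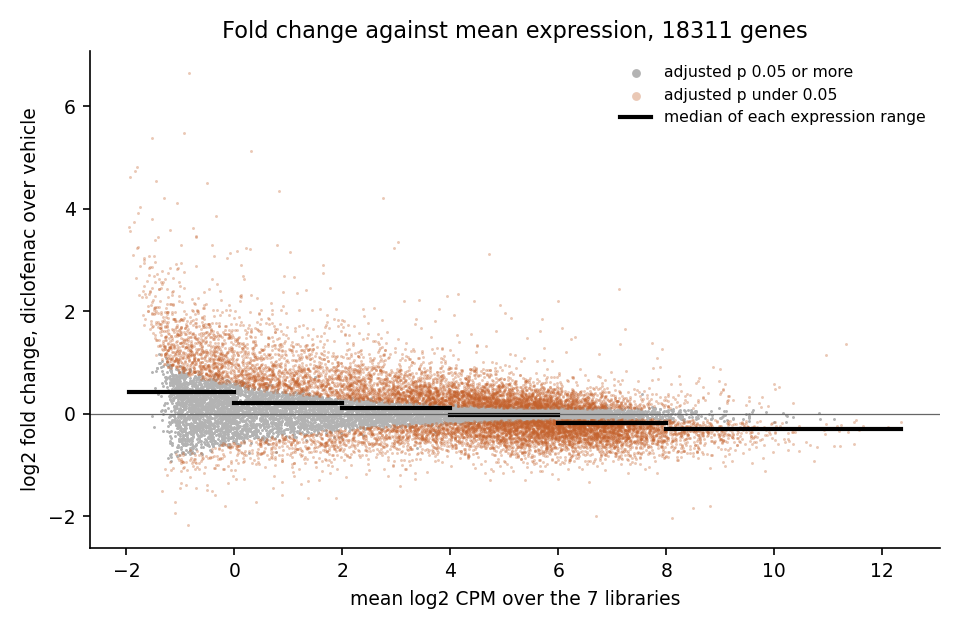
Log2 fold change, diclofenac over vehicle, against the mean log2 CPM over the 7 libraries for the 18311 tested genes (1 point each); black bars give the median of each expression range. The medians run from 0.423 below 0 log2 CPM to -0.291 at 8 log2 CPM or more.

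The largest rises among well-expressed genes were those of ARRDC3, MALAT1, SLC16A9, DDIT3, NEAT1 and SLC6A9. ARRDC3, an arrestin-domain adaptor protein, rose from 7.63 ± 0.384 to 66.1 ± 2.57 normalized CPM (log2 fold change 3.12, SE 0.0640, edgeR adjusted p = 5.08e-16). MALAT1 and NEAT1, long non-coding RNAs kept in the nucleus, rose by 2.44 (SE 0.0764) and 2.20 (SE 0.0577) on the log2 scale. DDIT3, the stress-response transcription factor CHOP, rose 4.61-fold, the glycine transporter SLC6A9 rose 4.37-fold and the transporter SLC16A9 rose 5.08-fold. The largest falls included CENPX, a centromere and DNA repair protein (161 ± 14.2 to 64.1 ± 3.78 normalized CPM, log2 fold change -1.33, SE 0.0585), and ENDOG, a mitochondrial nuclease (log2 fold change -1.29, SE 0.0702). The other falls were 4 rows with clone-based names, FP236383.5, FP236383.4, FP671120.7 and FP671120.8, at log2 fold changes of -2.03, -1.98, -1.84 and -1.79. These rows had no match in the annotation used, and their vehicle levels were uneven, from 344 to 1075 normalized CPM for FP236383.5.

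Glycolytic transcripts fell together. Of 22 members, 19 fell and none rose, both over all genes and adjusted over the list alone, and ENO2, SLC16A3 and PFKFB4 did not pass the test. The list median was a fold of 0.629, camera adjusted p = 3.95e-09. PKM fell by 0.92 (SE 0.0466) and GPI, which converts glucose 6-phosphate to fructose 6-phosphate, fell by 0.89 (SE 0.0424) on the log2 scale. All 21 tricarboxylic acid cycle genes fell (21 adjusted over the list alone; median fold 0.733, camera adjusted p = 3.56e-10), among them IDH3G, a subunit of isocitrate dehydrogenase, by 0.64 (SE 0.0487). SDHA of succinate dehydrogenase fell by 0.66 (SE 0.0496), with the caution that its pseudogene rows hold counts equal to 40.4% of its own. Both lists kept an adjusted p = 0.0184 with an estimated correlation. The metabolic lists, here and below, are themes that the title names and no independent evidence of direction.

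Of 50 nuclear genes of the respiratory chain and ATP synthase, 46 fell and none rose (47 fell adjusted over the list alone; median fold 0.721, camera adjusted p = 3.37e-16). Here the call was lost, with an adjusted p = 0.168 with an estimated correlation. ATP5F1D and ATP5MC1, subunits of ATP synthase, fell by 1.09 (SE 0.0536) and 0.92 (SE 0.0480) on the log2 scale. The 13 mitochondrially encoded mRNAs moved the other way, all rising (13 adjusted over the list alone; median fold 1.48, camera adjusted p = 1.19e-04, but adjusted p = 0.456 with an estimated correlation). MT-CO1, a catalytic subunit of cytochrome oxidase, rose from 1265 ± 134 to 2814 ± 329 normalized CPM. Their share of all counts was 0.629 ± 0.0845% under vehicle and 1.11 ± 0.159% under diclofenac, and that of the mitochondrial ribosomal RNAs 0.176 ± 0.0225% and 0.472 ± 0.0368%. Each share had an exact permutation p of 0.0286 and an adjusted p of 0.0572.

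Lipid metabolism was mixed. Of 24 tested cholesterol synthesis genes, 6 rose and 11 fell (6 and 12 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.104); its median, -0.131 on the log2 scale, turned to 0.0503 under scaling by total counts alone. ACAT2 and MVD, enzymes of the pathway, fell by 0.94 (SE 0.0488) and 0.64 (SE 0.0510). Of 13 fatty acid synthesis genes, 4 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.797), but 8 rose and 3 fell by total counts alone, which turned the median from -0.0199 to 0.162. ACLY, which makes cytosolic acetyl-CoA from citrate, fell by 0.73 (SE 0.0483). In the list of fatty acid oxidation and PPAR targets, 4 of 21 rose and 14 fell (4 and 14 adjusted over the list alone; camera adjusted p = 0.00364, but adjusted p = 0.152 with an estimated correlation). PDK4, a kinase that restrains pyruvate dehydrogenase, rose by 0.84 (SE 0.117). Nucleotide synthesis genes fell, 17 of 19 with none rising (17 adjusted over the list alone; median fold 0.743, camera adjusted p = 3.68e-07 and adjusted p = 0.0184 with an estimated correlation), including IMPDH1 of guanine nucleotide synthesis by 0.75 (SE 0.0447).

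**Figure D3:**
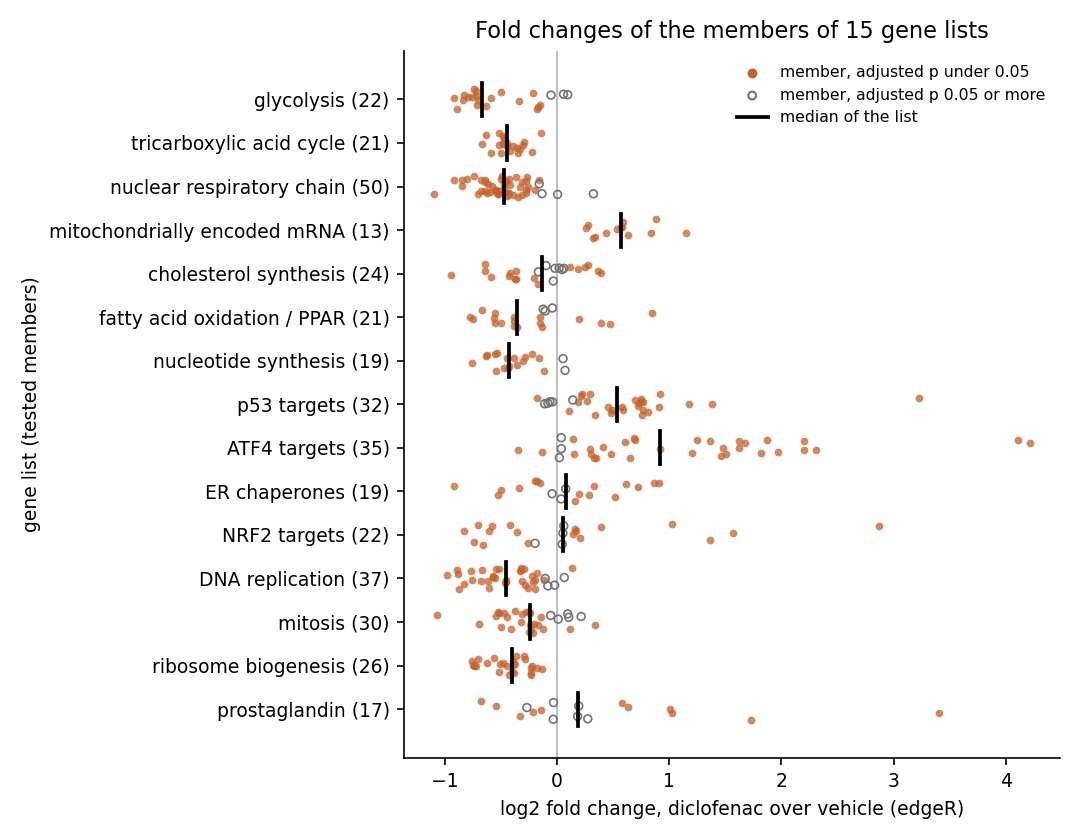
Log2 fold changes (horizontal axis) of the tested members of 15 gene lists; filled points passed an edgeR adjusted p of 0.05, open points did not, and black bars are list medians. The median is -0.668 for glycolysis and 0.916 for ATF4 targets.

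Targets of the tumor suppressor p53 rose: 26 of 32 were higher and 1, FDXR, was lower (26 and 1 adjusted over the list alone). The median fold was 1.45, camera adjusted p = 3.69e-09, and the call held at an adjusted p = 0.0184 with an estimated correlation. The title names this theme, so the count is not independent evidence of its direction. CDKN1A, the cell cycle inhibitor p21, rose from 66.4 ± 1.92 to 113 ± 3.76 normalized CPM (log2 fold change 0.77, SE 0.0458, edgeR adjusted p = 2.96e-10). GDF15, a secreted stress hormone, rose 9.38-fold (log2 fold change 3.23, SE 0.114). CDKN1A, GDF15 and SESN2 are all among 10 members also listed as stress-response genes, so none of them speaks for p53 alone. Without those 10, 17 of the remaining 22 rose and 1 fell, and the camera adjusted p was 7.33e-05. Among 14 tested regulators of the p53 family, 6 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.967), with median -0.0157 and mean 0.0157; the p53 inhibitor MDM4 rose by 0.76 (SE 0.0649).

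The targets of ATF4, the transcription factor of the integrated stress response, had the highest median of the 27 tested lists. Of 35 members, 30 rose, ALDH18A1 and EPRS1 fell and 3 did not pass (30 and 2 adjusted over the list alone). The median fold was 1.89, camera adjusted p = 3.37e-16, and the call held at an adjusted p = 0.00486 with an estimated correlation. NUPR1 rose by 4.21 (SE 0.129) and the hormone FGF21 by 4.11 (SE 0.411) on the log2 scale, FGF21 from 4 counts in all vehicle libraries to 108 in all diclofenac libraries. Chaperones of the endoplasmic reticulum did not move as a list: 9 of 19 rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.454), with SDF2L1 lower by 0.92 (SE 0.0709). Targets of NRF2, the oxidative stress factor, split 9 up and 9 down among 22 (9 and 9 adjusted over the list alone; camera adjusted p = 0.599), with median 0.05 and mean 0.124 above 0 but a camera direction below. The transporter ABCC2 rose by 1.57 (SE 0.197), and AKR1B10 went from 5 to 56 counts.

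**Figure D4:**
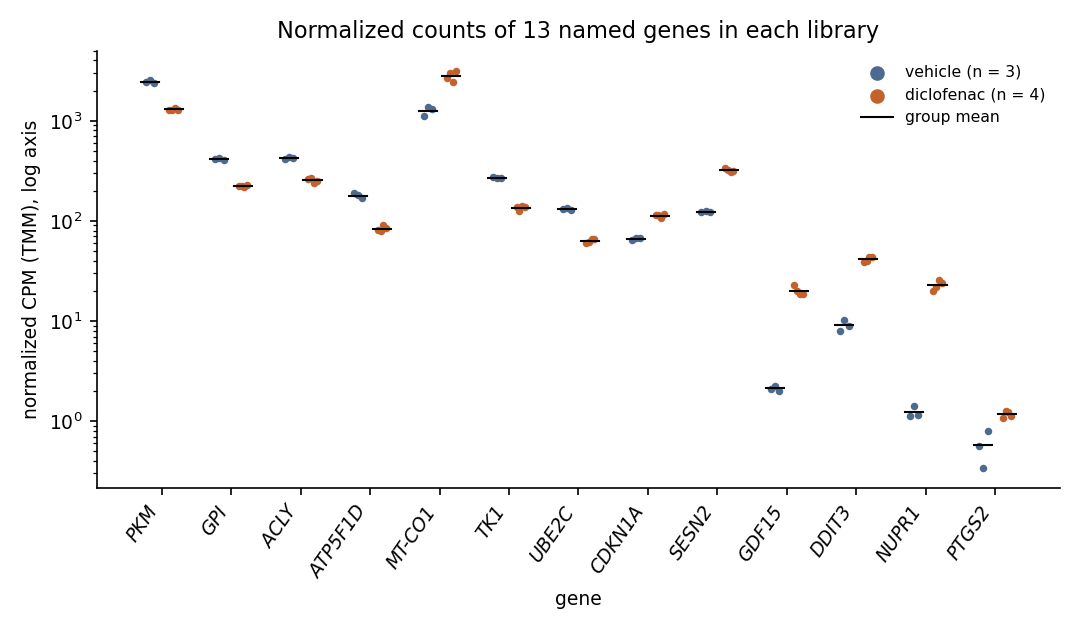
Normalized CPM (logarithmic axis) of 13 genes in the 3 vehicle and the 4 diclofenac libraries, 1 point per library, with group means as bars. PKM, GPI, ACLY, ATP5F1D, TK1 and UBE2C are lower and the other 7 genes higher in every diclofenac library than in any vehicle library.

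Genes of DNA replication fell, 32 of 37 with 1 rising (33 and 1 adjusted over the list alone; median fold 0.732, camera adjusted p = 3.13e-12 and adjusted p = 0.0292 with an estimated correlation). The replicative helicase subunit MCM5 fell from 425 ± 15.9 to 228 ± 7.67 normalized CPM, and TK1 fell by 0.98 (SE 0.0466). Of 30 genes of mitosis, 23 fell and 2 rose (23 and 2 adjusted over the list alone; median fold 0.846, camera adjusted p = 1.29e-05, but adjusted p = 0.0995 with an estimated correlation). Their fall was smaller: by total counts alone 12 fell and 6 rose, and the list median lay at the 16th percentile of 2000 random lists matched on mean expression. UBE2C, which acts with the anaphase-promoting complex, fell by 1.07 (SE 0.0467), the kinase CDK1 by 0.69 (SE 0.0443) and the proliferation marker MKI67 by 0.23 (SE 0.0489). For MKI67 the call was lost by total counts alone, at a log2 fold change of -0.05. All 26 genes of ribosome biogenesis fell (26 adjusted over the list alone; median fold 0.76, camera adjusted p = 2.58e-10, but adjusted p = 0.0517 with an estimated correlation), among them NOP16 by 0.76 (SE 0.0486).

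The cyclooxygenases, the targets of the drug, were weakly expressed. Of 2712 tested genes with a mean below 0 log2 CPM, such as PTGS2, 706 rose by at least 2-fold. The median log2 fold change of those 2712 was 0.423, so the rise of PTGS2 was not set apart from that trend. PTGS2 rose from 0.571 ± 0.232 to 1.18 ± 0.0878 normalized CPM (log2 fold change 1.02, SE 0.259, edgeR adjusted p = 0.00243), 39 counts in all vehicle and 115 in all diclofenac libraries. PTGS1 had too few counts to be tested, with 1 count in all vehicle and 40 in all diclofenac libraries, a ratio of count rates of 31.4 (95% exact Poisson interval 5.32 to 1270, counting error only). The prostaglandin list did not pass, with 6 of 17 higher and 5 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.878). The list median of 0.185 on the log2 scale lay at the 64.8 percentile of random lists matched on mean expression (central range -0.172 to 0.492). The prostaglandin transporter SLCO2A1 rose by 1.73 (SE 0.251), and the receptor PTGER3 went from 4 to 66 counts.

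Of 25 NF-kB and cytokine genes 13 were tested, of which 7 rose and none fell (7 adjusted over the list alone). The camera adjusted p was 0.0206, but 0.201 with an estimated correlation. The list median of 0.558 on the log2 scale lay at the 92.4 percentile of random lists matched on mean expression. It was inside their central range of -0.124 to 0.674, so the rise was not set apart from the trend with expression level. The chemokine CXCL8 went from 7 counts in all vehicle to 76 in all diclofenac libraries. Interferon response genes split 5 up and 4 down among 15 (5 and 4 adjusted over the list alone; camera adjusted p = 0.797), with median -0.0357 and mean 0.174; BST2 rose by 2.01 (SE 0.263) from 0.409 normalized CPM. In xenobiotic metabolism 5 of 13 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.573), with CYP1A1, a target of the aryl hydrocarbon receptor, higher by 1.98 (SE 0.245).

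Other lists moved in both directions. Apoptosis regulators split 8 and 8 among 24 (8 and 8 adjusted over the list alone; camera adjusted p = 0.994), with median and mean above 0 but a camera direction below, and BID, which links death receptors to mitochondria, fell by 0.70 (SE 0.0587). Lysosome and autophagy genes split 9 and 9 among 26 (9 and 10 adjusted over the list alone; camera adjusted p = 0.797; median 0.0338, mean -0.00285), and ATG9B rose by 1.37 (SE 0.241). Hypoxia genes split 6 and 6 among 18 (6 and 6 adjusted over the list alone; camera adjusted p = 0.797; median 0.0444, mean -0.00679), although the angiogenic factor VEGFA rose from 26.1 ± 0.638 to 53.7 ± 2.83 normalized CPM. Of 15 mesenchymal transition genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.256), with SPARC going from 10 to 59 counts. The near-even splits here and above depended on the scaling. By total counts alone, 12 rose and 5 fell among apoptosis regulators, 16 and 7 among lysosome and autophagy genes, 10 and 3 among hypoxia genes and 12 and 4 among endoplasmic reticulum chaperones. On that scale NRF2 targets gave 12 rises and 8 falls, interferon response genes 7 and 3, xenobiotic metabolism 7 and 1, the prostaglandin list 7 and 2 and the regulators of the p53 family 8 and 3.

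Squamous lists could be read only in part. Of the 6 tested differentiation genes, 3 rose (ECM1, PPL and GRHL3) and 2 fell (KRT10 and CNFN), the same adjusted over the list alone (3 and 2), camera adjusted p = 0.629; by total counts alone 3 rose and none fell. ECM1 rose by 0.99 (SE 0.162) and PPL by 1.00 (SE 0.285), both under 5 normalized CPM. The basal list rose, with 10 of 15 higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.00922, but adjusted p = 0.0943 with an estimated correlation), and its untested members were KRT5, KRT14, KRT15, TP63 and COL17A1. The genes that rose were mostly integrins, which many adherent cells carry, laminins and receptors. The largest rise in the list was that of the neurotrophin receptor NGFR (2.11 ± 0.169 to 21.7 ± 1.03 normalized CPM). Markers of other cell types were low, apart from COL1A1 at 15.8 ± 1.09 CPM under vehicle. Of 5 tested fibroblast genes, 1 rose (COL6A3) and 1 fell (COL1A1), the same adjusted over the list alone (1 and 1; camera adjusted p = 0.797). Of 4 tested immune genes, ITGAM, CSF1R and CD14 rose (3 adjusted over the list alone), all under 2 CPM, and neither of the 2 tested endothelial genes passed, over all genes or adjusted over the list alone. Of 3 tested hemoglobin and liver genes, ALB rose from 1 to 55 counts, and HBA1 and HBA2, near-identical copies whose reads can be shared, fell (1 and 2 adjusted over the list alone), but by total counts alone neither fall was called.

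For each of the 53 tested genes named by the rule, every diclofenac library lay on the same side of every vehicle library, which follows in large part from the choice of genes by size of change or lack of overlap. Any unrecorded difference in handling between the groups would be part of these contrasts.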

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

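None of the tests in this part was chosen after its result was seen. In the group of 4 diclofenac libraries, 60 measures were searched for a single library far from the others (Dixon's test), and chance would place about 1 in 20 of such groups beyond it. There were 3. PKM stood at 1340 normalized CPM in diclofenac replicate 3, with a gap of 0.836 of the range to the nearest library, against a group mean of 1297 ± 28.5. ABCC2 stood at 3.47 normalized CPM in diclofenac replicate 1 (gap 0.847 of the range), against a mean of 2.84 ± 0.428. MDM4 stood at 34.8 normalized CPM in diclofenac replicate 2 (gap 0.882 of the range), against a mean of 33.6 ± 0.769. All these values lie on the same side of every vehicle library as the other 3 libraries of the group.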

How the results depend on the processing

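Scaling by total counts alone, pseudogene rows left out, upper-quartile factors for the named genes and the shortened p53 list were chosen after the data were seen. Genes called higher and lower, 5535 and 5402, became 8635 and 3029 by total counts alone, which follows from its shift of all fold changes by 0.181, and 1194 and 109 with a minimum of 2-fold. With pseudogene rows left out 5057 and 5083 were called, and with DESeq2 4181 and 5182. Leaving out each library gave 4869 to 5313 higher and 5019 to 5397 lower, and 5 lists higher and 8 lower each time. With the replicate number as a block 4915 and 5003 genes and 5 and 8 lists were called, and no list or named gene changed its call. The deviations of same-numbered libraries correlated at 0.000867, 0.0216 and -0.0474, and vehicle replicate 1 correlated best with diclofenac replicate 3 (0.0721). These values show no sign that the numbers pair the samples, but they cannot exclude a shared day, which the labels leave open. With an estimated correlation, 2 lists were higher and 4 lower, and the camera adjusted p rose to 0.152 (fatty acid oxidation), 0.456 (mitochondrial mRNA), 0.0995 (mitosis), 0.201 (NF-kB), 0.168 (nuclear respiratory chain), 0.0517 (ribosome biogenesis) and 0.0943 (squamous basal); for NF-kB it was also 0.102 under the stricter filter. With fry, which does not compare a list with other genes, 12 lists were higher, and the adjusted p passed for cholesterol synthesis (2.95e-05), mesenchymal transition (2.17e-04), endoplasmic reticulum chaperones (0.00347), fibroblast genes (0.0363), hypoxia (0.00888), NRF2 (0.00309), squamous differentiation (0.0106), p53 regulators (0.00557) and xenobiotic metabolism (1.29e-04). Apart from the construction of each setting, the cause was not tested. Of 784 values of the 53 named genes, 782 kept direction and call; MKI67 lost its call by total counts alone (log2 fold change -0.05) and PPL with DESeq2 (0.97). A pseudocount alternative was not run, since the values are counts. In the simulation 24 of 50 changes of the smallest size were recovered. With few changed genes its threshold was stricter than in these data, so the recovery here is not known from it. Changes of that size that were not called remain open.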

Other observations

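Chosen after the result was seen were the tests on squamous genes, the scaling tests, the depth comparison, the p53 list without shared members, the gene classes and the matched random lists other than that for p53.

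Families of genes defined by symbol alone moved as groups outside the fixed lists, but none was set against random lists matched on mean expression. The median log2 fold change of all tested genes ran from 0.423 under 0 log2 CPM to -0.291 at 8 or more. How far the family moves go beyond that trend was therefore not tested. Mitochondrial ribosomal proteins fell, 67 of 77 with none rising (median fold 0.78), as did 28 of 34 proteasome genes with none rising (0.759), all 8 subunits of the cytosolic chaperonin (0.72) and 11 of 15 tubulins with 1 rising (0.69). Of 80 cytosolic ribosomal proteins 61 fell and 5 rose (0.825), of 13 subunits of RNA polymerase II 8 fell and 2 rose (0.828), and of 40 importins and nucleoporins 23 fell and 3 rose (0.878). Of 44 mitochondrial carriers 20 fell and 8 rose (0.9). By total counts alone 27 cytosolic ribosomal proteins fell and 13 rose, 12 importins and nucleoporins fell and 11 rose (median log2 fold change -0.188 before and -0.00672 then), and 14 carriers fell and 13 rose, with their median turning from -0.152 to 0.029. Zinc finger genes named ZNF rose, 239 of 432 with 50 falling (1.18), and so did 17 of 29 replication histones with 6 falling (1.35). All 10 families passed at a camera adjusted p under 0.05, from 2.39e-17 to 0.0139, and none did with an estimated correlation, from 0.0686 to 0.297.

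By gene class, long non-coding genes rose more often than they fell, 842 against 156 of 2022 tested with 342 and 10 by at least 2-fold. Their median log2 fold change of 0.38 was close to the 0.423 of all genes under 0 log2 CPM, and their rise was not tested apart from expression level. Protein-coding genes split 4215 against 4602 of 13590, and pseudogenes went the other way, with 369 higher and 608 lower of 2359 (median -0.103). Set against 2000 random lists matched on mean expression, the medians of glycolysis, the tricarboxylic acid cycle, the nuclear respiratory chain and DNA replication lay at the 0 percentile and that of ATF4 targets at the 100 percentile. Nucleotide synthesis lay at 0.3, ribosome biogenesis at 0.25, mitosis at 16 and NF-kB and cytokine genes at 92.4. Endoplasmic reticulum chaperones (99.8) and NRF2 targets (98.5) lay high among lists of their expression level although camera did not call them.

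The floor of several squamous genes in libraries labelled as squamous carcinoma is the pattern a reader may most want to follow up. A mispairing of row names and counts is argued against by 21 of 21 tricarboxylic acid cycle genes called in the same direction, and loss of keratin reads to near-identical copies by TP63, CDH1, EPCAM, GRHL2 and TRIM29, which are no keratins and reached at most 3.48 CPM. Another cell type remains possible: KRT5, KRT14, KRT6A and TP63 reached at most 0.151 CPM, but 13 of the 20 basal genes were at 1 CPM or more in every library, above the limit set for that test though near the share of all coding genes (61.1%), and loss of squamous identity in this line stays open. Of 13 further epithelial and squamous genes, picked after the data were seen, 3 were at 1 CPM or more in every library and 0 at 10 or more. Their median percentile among coding genes was 22.2. A candidate explanation is an embryonic kidney line, since 26 of 33 genes listed for it were at 1 CPM or more in every library (61.1% of all coding genes were). At 10 CPM or more in every library were 18 of the 33, and the median percentile of that list was 71.1. Among the 33 were HOXB9 at 377, NEFL at 146 and LIN28B at 53.6 CPM under vehicle. NOG and RSPO1, at 2130 and 920 CPM (ranks 16 and 80 of all rows in vehicle), were noticed for their high level. They are not in that list and were not counted for it. What their level says about the cells cannot be read without a reference profile. Against a kidney line, NR0B1 and CDH6 had no count in the vehicle libraries. PAX8, LIN28A and SALL4 stood at 0.0252, 0.055 and 0.112 CPM there, all members of the list. Several of the 33, among them HMGA1, HMGA2 and TBX3, are common in carcinoma lines and ENO2 is also in the glycolysis list, so without a reference profile this cannot be told apart from other lines. For this pattern no biological explanation was tested beyond the question of which cells the libraries hold.

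The excess of 2-fold rises, 1194 against 109, is argued not to come from deeper sequencing, since the mean total count of the diclofenac libraries minus that of the vehicle libraries was -1068726. Genomic DNA is argued against by olfactory receptor genes, whose mean gain per kilobase of exon the median raised gene exceeded 90.7 times (bootstrap interval 54.4 to 186), although their summed level also rose, from 4.24 to 7.95 CPM. A single scaling factor per library, which moves all genes alike, is argued against for the place of the rises among weakly expressed genes: the median log2 fold change under 0 log2 CPM exceeded that at 8 or more by 0.714 (bootstrap interval 0.672 to 0.762). The filter asked for 3 libraries, which 3 of the 4 diclofenac libraries or all 3 vehicle libraries could supply. This may favor rises among the weakest genes, and its part in that difference was not tested. The 2-fold raised genes had a median of 0.382 CPM under vehicle and 1.17 CPM under diclofenac. Farther from the filter the medians still differed, at 0.113 for 2 to 4 log2 CPM and -0.291 for 8 or more. For the excess of rises itself scaling stays open. Rises were at least 10.3 times as many as falls under DESeq2 size factors, upper-quartile factors and total counts alone, but these moved the median log2 fold change by -0.0099, 0.0881 and 0.181, so that none pushed far against the rises. A downward move of all fold changes by 0.423, which sets the median of genes under 0 log2 CPM to 0, would give 0.462 times as many rises as falls (550 against 1190, and 1665 against 11545 genes called at any size). That move was chosen to work against the rises and supports no scale of its own, and these counts hold no outside standard to set one. More unspliced RNA stays open: the share of sense-intronic genes was 1.22 times that of vehicle, between the limits set for and against it. A response to the drug that reaches many weakly expressed genes is a hypothesis that these values leave open.

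The rise of p53 targets is not carried by the 10 members also listed as stress-response genes alone. Without those 10 the camera adjusted p was 7.33e-05 (0.0306 with an estimated correlation) and the median log2 fold change 0.377. Nor does the rise follow the trend with expression level, as the list median of 0.536 lay at the 100 percentile of 10000 matched random lists. Their central range was -0.204 to 0.0786. Activation of p53, whose signaling the title of the series names, may account for the rise, but the identity of the cells bears on it, and transcript levels alone leave other regulators of these genes open.

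Of the 35 splits of the 7 libraries into 3 and 4, only the real one called 10937 genes (1 of 35, a share of 0.0286, the smallest these splits allow), and the highest count in any other split was 0. Chance is excluded for the count of genes by edgeR at that share and no further, since a mixed split puts the difference between the groups into its residual spread. At an unadjusted p under 0.05 the real split gave 11614 genes and the highest of the others 6722. For the count of 13 gene lists chance is not excluded: 5 of the 35 splits, the real one included, called as many lists, and the highest of the others was 13. Each of those others differed from the real split by the exchange of 1 library of a group, or by 1 library changing sides with the groups mirrored, and so carries most of the treatment contrast. Of the 10 families named by symbol all 10 passed, as the hypothesis that housekeeping families move together needs, under the preset correlation alone. They were not matched on expression level.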
